A study of Mus musculus with 2 samples.

How the data were processed

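DNase-seq was performed on nuclei from the urinary bladder of male B6CASTF1/J mice aged 36 days, with 2 libraries from separate animals, named replicate 1 and replicate 2 after the labels. Per the labels and the text deposited with each library, the authors made every list separately for each library from its filtered alignments to the mouse assembly mm10, together with a mappability reference; replicates were not pooled. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. The animals are F1 hybrids, and the mm10 assembly represents C57BL/6J only, so reads of the other parental genome were placed on a reference that differs from them.

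The peak height is a signal value that the authors deposited for each peak. No header states its scale. From the values, heights are whole multiples of 0.0113 in replicate 1 and of 0.00893 in replicate 2, for 100% of the low heights within a tolerance of 0.05 of a step, and they were treated as counts scaled by a constant per library. The absolute read depth is unknown, and no interval that needs it is given. The authors deposited a pair of peak lists per library, and the FDR threshold of each was taken from the values: every peak of the shorter list held a stretch with a deposited per-site FDR of at most 0.001, and every peak of the longer list one of at most 0.05. The shorter list was used as the main list by a rule for stricter lists, and the longer one as an alternative. The per-site FDR values that the authors deposited are p-values adjusted for multiple testing, listed for stretches of bases up to 0.05, per the values. The footprint lists carry the same deposited value, 0.01, for each footprint and hold no strength of their own. It was read as a limit on a p-value or on an FDR, and neither the labels nor the deposited text say which.

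Peaks were compared by position with the GRCm38 patch 6 sequence and the GENCODE M21 annotation, which share coordinates with mm10. A start peak overlapped the 500 bases on either side of any of 132721 annotated transcription starts. A distal peak overlapped no such window and was assigned to each gene with a start within 50 kb of its midpoint. Peaks counted as shared when they overlapped by at least 1 base, and chance overlap came from 100 shuffles of 1 list within each chromosome. Spearman and Pearson correlations were taken across shared sites on log10 heights, and sites are not independent replicates, so no p-value is given.

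There were 24 gene lists, which covered urothelium, smooth muscle, fibroblasts, endothelium, pericytes, myeloid cells, lymphocytes, glia, mesothelium, adipocytes, prostate and seminal vesicle, skeletal muscle, cardiomyocytes, hepatocytes, neurons, photoreceptors, housekeeping genes, immediate early genes, urogenital patterning, bladder function, steroid receptors and anterior, central and posterior Hox genes. For each list, the share of genes with a start peak and the mean number of distal peaks were set against 10000 random lists of the same size drawn from 21938 protein-coding genes, matched on the decile of other starts within 50 kb. A list was called above or below random lists when its percentile was over 97.5 or under 2.5 in replicate 1, in replicate 2 and in the shared peaks. The random lists were not matched on the base composition of promoters, nor on the number or spacing of a gene's own starts. For each gene, the start peak percentile is the rank of its strongest start peak among all start peaks of its library, set to 0 where it had none. That peak could lie at any annotated start of the gene, including a start inside it. Genes are not replicates, so the percentiles describe these libraries and no p-value across genes was computed.

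For 36 consensus sequences, the share of footprints that held the consensus, after extension by 5 bases on each side, was divided by the share of windows of the same width 100 bases away that touched no footprint. These flank windows were not required to lie within a peak. With a median peak width of 200 bases, a flank could fall outside the accessible site of its footprint. Intervals are exact Clopper-Pearson 95% intervals of the split of hits, and they cover counting error only. A motif was called when the interval lay on 1 side of 0 and the ratio was at least 1.2-fold in both libraries. Shared distal peaks near 5 of the gene lists were also searched for the 36 consensus sequences, against 1000 random lists. A consensus match shows neither that a factor was bound nor which member of a factor family it would be.

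The named genes were set by rule: up to 5 genes per list with the highest mean start peak percentile, up to 3 with start peaks in both libraries for lists of other tissues, members of the urothelium, smooth muscle and Hox lists with no start peak, and the 15 protein-coding genes with the most shared distal peaks, at most 1 per 100 kb. Not every gene that this rule selects is reported here. Groups, gene lists, motifs, the rules for calls and names, and all alternatives except those said to be added were fixed before the data were examined. These alternatives were the longer peak list, the stronger 50% of each list, lists of equal length, 50% reciprocal overlap, start windows of 1000 and 250 bases, starts of protein-coding genes only, distal windows of 10 and 100 kb, random lists without matching, flanks at 50 and 200 bases, no extension of footprints, footprints away from starts, per-site FDR limits of 0.01 and 0.001, and each library left out. The alternatives added after the data were seen were distal sites near tRNA genes left out, distal sites counted once per list, the AP1 consensus in sites of a single library with lists of equal length and with the longer list of the other library, and consensus sequences set against up to 20 shuffles of their own letters in 2 forms. With 1 group of 2 libraries, no test between conditions and no paired test was made. Values are given per library or as mean ± SD (n = 2).

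The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9. The gene list step was tested on simulated data: of 200 random lists of 20 genes out of 21938, 2.5% were called above and 3% below, and with 2 sites planted per gene 100% were called above. These simulated list calls rested on shared distal peaks alone, not on each library as well. In the motif step, 3% of simulated ratios without an effect were called. Each such call rested on 1 ratio, not on both libraries. The simulated windows and flanks had the same base composition, unlike real footprints and flanks, so errors from composition were not covered. With a planted log2 ratio of 1.00, the median estimate was 0.91, 100% were called and the interval covered the planted value in 97%. Reads, alignments and allele-specific signal were not analysed here.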

Results

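DNase-seq, in which the nuclease DNase I cuts chromatin where it is accessible, was carried out on urinary bladder tissue of male B6CASTF1/J mice aged 36 days. These animals are F1 hybrids of the laboratory strain C57BL/6J and the wild-derived strain CAST/EiJ. The bladder wall holds urothelium, the epithelium that lines its lumen, together with detrusor smooth muscle, stromal fibroblasts, vessels, nerves and immune cells, so each library is a mixture of cell types. The design has 1 group with 2 libraries from separate animals and no other condition. The comparisons it implies are between the replicates, and between classes of genes and sequences within each library. Peak heights came in steps of 0.0113 in replicate 1 and 0.00893 in replicate 2. If 1 step stands for 1 read, replicate 2 was 1.27 times deeper, while the absolute depth is unknown.

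Accessible sites of the bladder lay far more often at transcription starts than shuffled sites did, and most of those found in replicate 1 were also found in replicate 2. Replicate 1 had 38674 peaks and replicate 2 had 47661, with a mean of 43168 ± 6355 (SD, n = 2) and a ratio of 1.23. The peaks covered 8.47 and 10.2 Mb (9.32 ± 1.2 Mb, SD, n = 2), and the median width was 200 bases in each library. Start peaks made up 50.6% of the list in replicate 1 and 42.7% in replicate 2 (46.7% ± 5.65, SD, n = 2), against 4.15% and 4.10% of shuffled peaks. Introns held 22.7% and 27.1% of peaks and intergenic sequence 22.2% and 25.7%, both below the shares of shuffled peaks, which were 41.5% and 41.5% for introns and 50.5% and 50.6% for intergenic sequence. Exons away from starts held 4.50% and 4.54%. The bases with a per-site FDR of at most 0.05 summed to 22.0 Mb in replicate 1 and 27.1 Mb in replicate 2.

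Sites called in both libraries were higher than those called in only 1. Of the replicate 1 peaks, 86.1% overlapped a replicate 2 peak, and 69.6% of the replicate 2 peaks overlapped a replicate 1 peak, against means of 0.886% and 0.727% for shuffled lists. In lists of equal length the shares were 79.4% and 78.6%. Merging both lists gave 51228 sites, of which 31612 (61.7%) were present in both libraries. Across these shared sites the heights had a Spearman correlation of 0.935 and a Pearson correlation of 0.940 on the log10 scale, and the log2 ratio of heights had an SD of 0.32. Sites are not independent replicates, so these coefficients carry no p-value. Median heights at shared sites were 1.67 in replicate 1 and 1.54 in replicate 2, while the 5254 sites of replicate 1 alone had a median of 0.828 and the 14362 sites of replicate 2 alone 0.723. Distal sites made up 77.9% of those found in replicate 2 alone, 56.4% of those in replicate 1 alone and 49.2% of the shared ones. Of the sites of a single library, 56.1% (replicate 1) and 56.9% (replicate 2) overlapped a peak in the more permissive list of the other library.

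Urothelial genes carried many distal accessible sites in both animals. The 29 genes of the list had a mean of 3.55 distal peaks within 50 kb of a start in replicate 1 and 4.86 in replicate 2. Shared distal peaks averaged 2.72 per gene, 2.14-fold the median of 1.28 for random lists (percentiles 100, 100 and 99.995 in replicate 1, replicate 2 and shared peaks). With each site counted once per list, an alternative added after the values were seen, the shared mean was 2.34 and the percentile 99.9. At the starts, 19 of 29 urothelial genes had a peak in both libraries (65.5%, percentile 87.1), which was not a call, although replicate 2 alone had 23 of 29 (percentile 99.3) and the more permissive peak list gave a call above random lists (percentile 99.9). The strongest start peaks of the list belonged to Klf5, a transcription factor of epithelial progenitors, with a start peak percentile of 84.9 ± 6.41 (SD, n = 2), and to Cldn4, a tight junction protein, with 68.9 ± 2.0. Cdh1, which encodes E-cadherin, reached 65.4 ± 8.26, and the epithelial transcription factors Grhl2 and Elf3 reached 57.3 ± 4.15 and 56.6 ± 6.46. The Klf5 peak of replicate 1 lay on chromosome 14 at 99298421 to 99298800, over the start of the gene at 99298691, and the Grhl2 peak on chromosome 15 at 37232901 to 37233360, over the start at 37233036. No start peak was found in either library for Ehf, Krt15, Krt20, Shh, Trp63 and Upk3b. The uroplakin genes Upk3a at 51.8 ± 4.64, Upk2 at 47.4 ± 8.40, Upk1b at 35.8 ± 7.13 and Upk1a at 29.2 ± 13.03 had start peaks in both libraries, and these 4 were chosen after their values were seen. Krt8 and Krt18, keratins of simple epithelia, had 10 and 9 shared distal peaks. They are neighbours on chromosome 15 whose windows overlap, and both were chosen after their values were seen.

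Smooth muscle genes ranged from strong start peaks to none. Tpm1, a tropomyosin with several promoters, had a start peak percentile of 96.0 ± 0.796 (SD, n = 2), at an annotated start inside the gene on chromosome 9 (67043801 to 67044140 in replicate 1). The intermediate filament gene Synm followed with 84.9 ± 3.54, Tpm2 with 70.4 ± 0.0563, Smtn with 66.4 ± 9.22 and Csrp1 with 59.0 ± 5.18. No start peak was present in either library for 11 of the 20 genes: Acta2, Actg2, Chrm2, Cnn1, Des, Kcnmb1, Ldb3, Lmod1, Myocd, Pgm5 and Tagln. The contractile genes Mylk, at 56.9 ± 6.14, and Myh11, at 34.7 ± 6.54, and the gene Synpo2, at 18.8 ± 5.80, had start peaks in both libraries and were chosen after their values were seen. In all, 8 of 20 had a start peak in both libraries (percentile 7.54, and 64.0 with the more permissive peak list, neither a call), and the mean number of shared distal peaks was 2.00 against 1.30 for random lists. The distal percentiles were 95.8, 98.6 and 96.3, which is not a call, whereas the more permissive peak list gave one at percentile 99.9.

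No stromal, vascular or nerve list was called for start peaks or distal peaks. Among fibroblast genes 7 of 20 had a start peak in both libraries (percentile 7.72, and 76.1 with the more permissive peak list, neither a call), led by the collagen gene Col1a1 at 66.6 ± 4.44 and the growth factor receptor Pdgfra at 60.5 ± 3.15 (SD, n = 2), with 1.05 shared distal peaks per gene, the same as random lists. Endothelial genes had 5 of 18 start peaks (percentiles 2.55, 2.32 and 1.19), just short of a call below random lists, and calls were made with the stronger 50% of peaks (percentile 0.125), with unmatched random lists (0.89) and without replicate 1 (2.32). Vwf, the von Willebrand factor gene, led them at 54.95 ± 11.8, and their shared distal mean was 1.78 (percentile 91.7). Pericyte genes had 2 of 8 start peaks and 2.25 shared distal peaks (percentiles 6.30 and 96.6). The pericyte start percentile was 82.3 with the more permissive list, and with the stronger 50% of peaks it was 0.43 and a call below random lists. Glial genes had 5 of 12, and Prx, which encodes periaxin, a protein of myelinating Schwann cells, had a strong start peak at 99.2 ± 0.217. The distal percentiles of glia were 97.0, 97.7 and 98.1 with 2.42 shared peaks per gene, so that replicate 1 missed the threshold. Without replicate 1 glia was called above at 97.7, and no other alternative gave a call. Adipocyte genes had 3 of 8 start peaks (percentile 9.68) and distal peaks within the range of random lists (percentile 33.9). The peaks of Vwf, Pdgfra, Prx and Col1a1 lay at annotated starts inside the genes, not at the gene starts. In replicate 1 they began at 125603321, 75156241, 27508061 and 94937081, against gene starts at 125546774, 75152292, 27499324 and 94936224.

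Among immune and mesothelial lists, 2 of 3 were called below random lists for start peaks. Myeloid genes were called below random lists, with 2 of 14 start peaks in both libraries (14.3%, percentile 0.055). These were Irf8, a transcription factor of monocytes and dendritic cells, at 61.9 ± 4.50 (SD, n = 2) and Cd14, a co-receptor for bacterial lipopolysaccharide, at 34.7 ± 7.02. Their shared distal mean was 1.86 (percentile 89.9). Lymphocyte genes had 5 of 14 (percentile 3.36, no call) with Lck, a T cell kinase, at 67.5 ± 3.73 and Pax5, a B cell transcription factor, at 50.4 ± 0.985, and 2.07 shared distal peaks (percentile 90.2). With the stronger 50% of peaks and with start windows of 250 bases the lymphocyte list was called below, at percentiles 0.94 and 0.305. The Lck and Pax5 peaks lay at annotated starts inside the genes (129556521 to 129556720 and 44704441 to 44704620 in replicate 1). Mesothelial genes were called below with 1 of 8 (percentile 0.47) and 1.00 shared distal peaks (percentile 23.97). That call was lost with the more permissive peak list (percentile 21.1) and with unmatched random lists (0.875).

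Genes of tissues other than bladder mostly lacked start peaks. No gene had a start peak in both libraries among 15 neuron genes, 13 hepatocyte genes, 10 cardiomyocyte genes and 10 genes of prostate and seminal vesicle, and all 4 lists were called below random lists, with percentiles of shared peaks of at most 0.015. Skeletal muscle had 1 of 12 (percentile 0.02), the fast myosin light chain gene Mylpf, at 58.3 ± 0.509 (SD, n = 2). Photoreceptor genes had 2 of 11 (percentile 0.355), Opn1sw at 64.5 ± 3.45 and Gnat1 at 43.2 ± 2.46, which encode a cone opsin and the rod transducin. The cardiomyocyte call was lost with the more permissive peak list, although the percentile of shared peaks was 0.06 there. None of these 6 lists was called for distal peaks, although cardiomyocytes stood at 98.97 in replicate 2 and were called above without replicate 1. The shared distal means of the 6 lists ran from 0.80 for prostate and seminal vesicle (percentile 18.4) to 2.20 for cardiomyocytes (percentile 92.5), with 1.27 for photoreceptors, 1.38 for hepatocytes, 1.83 for skeletal muscle and 1.87 for neurons.

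**Figure D1:**
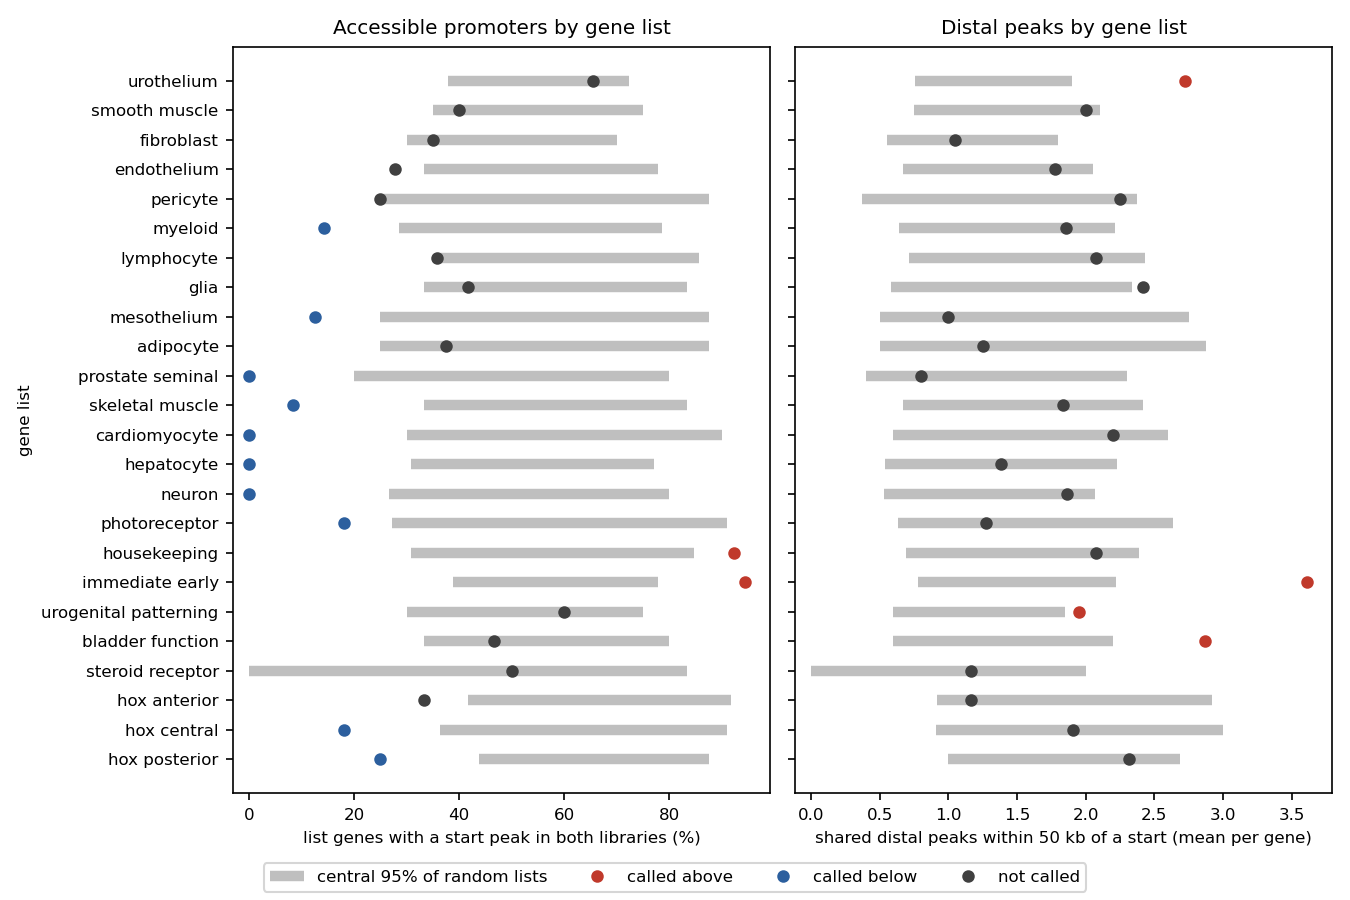
The left panel plots, for each of 24 gene lists, the percent of genes with a start peak in both libraries, and the right panel the mean number of shared distal peaks within 50 kb of a start. Grey bars span the central 95% of 10000 random lists. Points are the lists, red where called above, blue where called below and dark grey where not called. For distal peaks, urothelium (2.72), immediate early (3.61), urogenital patterning (1.95) and bladder function (2.87) stand to the right of their bars. Glia (2.42) also stands to the right of its bar, without a call.

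Immediate early genes, which respond within minutes to growth factors and stress, had the highest share of start peaks and the most shared distal peaks per gene of the 24 lists. A start peak was present in both libraries for 17 of 18 (94.4%), against 61.1% in the median random list (percentiles 99.95, 99.99 and 99.965), and the median start peak percentile of the list was 82.6 in replicate 1 and 88.0 in replicate 2. Jun and Jund, members of the AP-1 complex, reached 98.6 ± 0.258 and 98.5 ± 0.626 (SD, n = 2), and Egr1, Klf6 and Atf3 reached 95.8 ± 2.57, 95.3 ± 1.16 and 92.6 ± 0.266. The genes had 3.61 shared distal peaks on average, 2.60-fold the random median of 1.39 (percentile 100 in each library and in the shared peaks). Housekeeping genes were called above for start peaks, with 12 of 13 (percentile 99.6), led by Rplp0, a ribosomal protein gene, at 99.9 ± 0.124, Ppia at 98.9 ± 0.317 and Actb at 98.4 ± 0.0263. Their 2.08 shared distal peaks were not called (percentile 92.5). The start peaks of Atf3 and Actb lay at annotated starts inside the genes.

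Receptors and channels of bladder filling and emptying had more distal peaks than random lists. The 15 genes had 2.87 shared distal peaks on average, 2.26-fold the random median of 1.27 (percentiles 99.5, 99.9 and 99.9), and 2.73 with each site counted once (percentile 99.8). Start peaks in both libraries were found for 7 of 15 (percentile 27.5, with 69.7 in the more permissive list and 2.10 in the stronger 50% of peaks, none a call). Piezo1, a stretch-activated channel, had the strongest at 92.6 ± 6.62 (SD, n = 2), on chromosome 8 at 122551601 to 122551780 in replicate 1, beside the start at 122551329. The ATP receptor gene P2rx3 reached 61.3 ± 4.43, the water channel gene Aqp3 53.6 ± 1.10 and Piezo2 11.9 ± 11.0.

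Regulators of lower urinary tract patterning were called above random lists for distal peaks, with 1.95 shared peaks per gene against 1.15 (percentiles 99.96, 97.8 and 98.7). The call ended under 5 alternatives: the stronger 50% of peaks (98.1, no longer past the threshold in each library), windows of 10 kb (96.5) and 100 kb (94.0), unmatched random lists (94.96) and sites counted once (94.5). At starts 12 of 20 had a peak in both libraries (percentile 74.2). The T-box genes Tbx3 and Tbx2 had start peak percentiles of 83.9 ± 1.03 and 74.9 ± 9.07 (SD, n = 2), and Bmp4 and Gli2 reached 55.1 ± 1.38 and 52.0 ± 6.65. Of 6 steroid receptor genes, 3 had a start peak in both libraries (percentile 62.3) and 1.17 shared distal peaks (percentile 76.98). The mineralocorticoid receptor gene Nr3c2 reached 86.1 ± 4.03 and the glucocorticoid receptor gene Nr3c1 83.0 ± 5.41, while the estrogen receptor gene Esr1 reached 16.1 ± 0.666. In replicate 2 alone all 6 had a start peak (percentile 99.6).

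Start peaks of the Hox genes, which pattern the body axis from anterior to posterior, were found in the HoxA and HoxD clusters and almost nowhere else. Of 39 Hox genes, 11 had a start peak in replicate 1 and 17 in replicate 2. HoxA (chromosome 6, 52155590 to 52260880) had 6 and 8 of 11, HoxD (chromosome 2, 74668310 to 74765142) 4 and 6 of 9, HoxC (chromosome 15, 102921103 to 103036852) 1 and 1 of 9, and HoxB (chromosome 11, 96194316 to 96368256) 0 and 2 of 10. The strongest was at Hoxa7, with a percentile of 87.7 ± 4.20 (SD, n = 2), followed by Hoxa9 at 75.8 ± 4.30, Hoxa4 at 60.9 ± 7.65 and Hoxd8 at 60.3 ± 2.32. Hoxd3 and Hoxd4 shared a start peak at 52.7 ± 1.23, and Hoxa11, Hoxc10 and Hoxa13 lay between 38.5 and 44.8. Start peaks in both libraries were found for 4 of 12 anterior, 2 of 11 central and 4 of 16 posterior Hox genes, against random medians of 66.7%, 72.7% and 68.8%. The central and posterior lists were called below random lists (percentiles 0.03 and 0.025) and the anterior list was not, because replicate 2 gave 19.1. With the more permissive peak list both calls were lost, at shared percentiles of 2.62 and 3.79. Shared percentiles stayed low where a call was lost because a single library missed the threshold, at 0.21 and 0.12 with start windows of 1000 bases for both lists, and at 0.04 with the stronger 50% of peaks and 0.76 with unmatched lists for the posterior list. Shared distal peaks averaged 1.17, 1.91 and 2.31 per gene in the 3 lists (percentiles 9.65, 60.9 and 90.8), none a call, while unmatched random lists gave the posterior list a call above them (percentile 98.45). Within single libraries the anterior list stood at 95.2 and 99.99, the central list at 99.97 and 100 and the posterior list at 100 and 100. Neighbouring Hox genes share these sites, however. Counted once, the sites gave 40.15 and 73.9 for the anterior list, 44.2 and 66.7 for the central list and 13.6 and 26.1 for the posterior one. The shared peaks counted once gave 1.56 for the anterior, 2.68 for the central and 0.335 for the posterior list, none of them a call. Of the 24 distal peaks in the 4 clusters in replicate 1, 12 were shared, whereas 84.3% of all distal peaks were, and of the 37 in replicate 2, 13 were shared (35.1%), against 58.8% of all. Most of these peaks lay in HoxA, with 7 of 17 shared in replicate 1 and 8 of 15 in replicate 2, and in HoxB, with 2 of 4 and 2 of 17. HoxC had 2 of 2 and 2 of 3 shared, and HoxD 1 of 1 and 1 of 2.

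**Figure D2:**
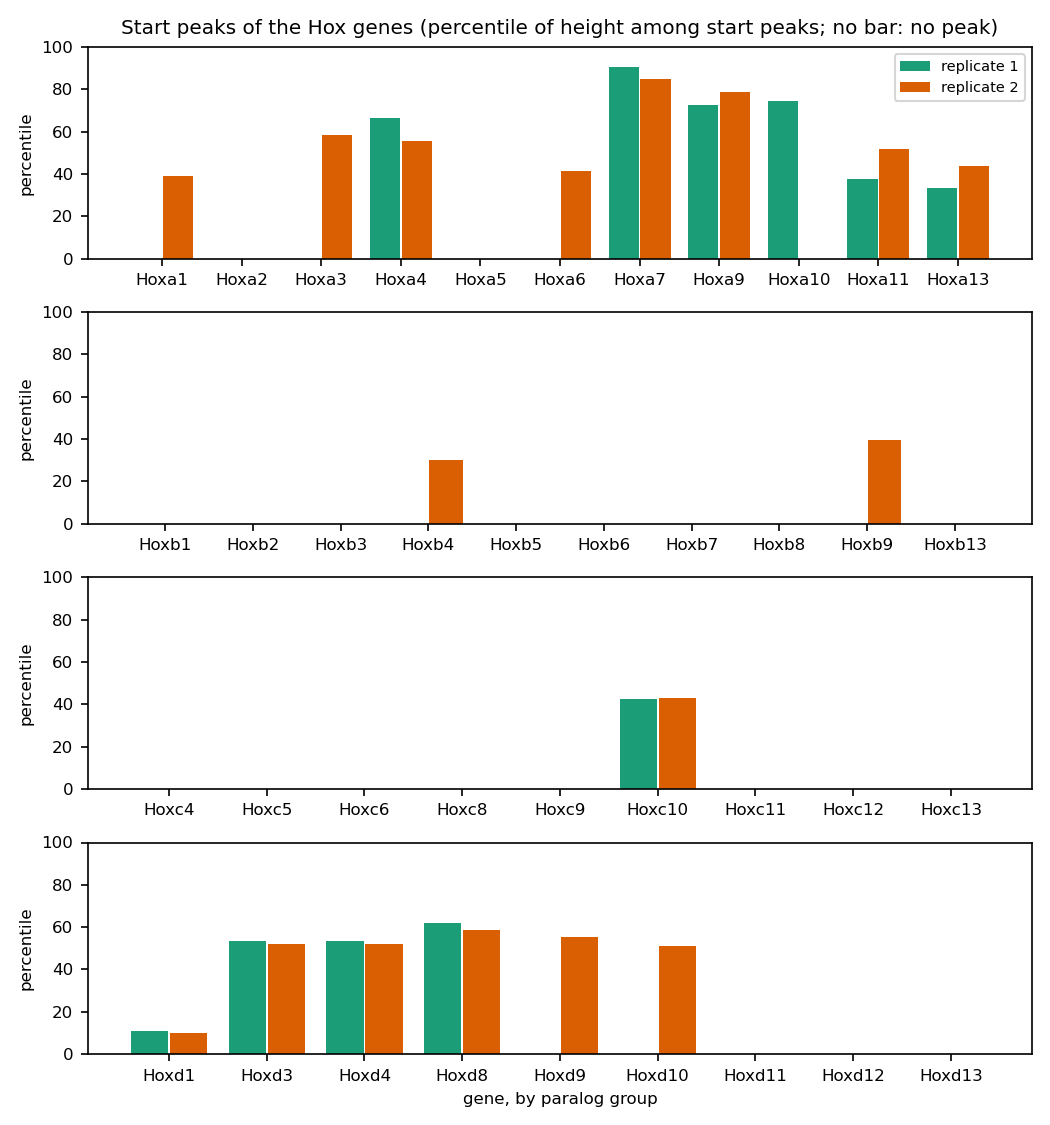
The panels show the HoxA, HoxB, HoxC and HoxD clusters from top to bottom, with genes in order of paralog group on the horizontal axis and the percentile of the strongest start peak among all start peaks of its library on the vertical axis (0 to 100). Green bars are replicate 1, orange bars replicate 2 and a missing bar means no peak; bars in both libraries are highest at Hoxa7.

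Across all 21938 protein-coding genes, 57.8% had a start peak in replicate 1, 58.6% in replicate 2 and 56.3% (12341 genes) in both. Distal peaks numbered 19086 and 27329, and 15562 distal sites were shared, with a mean of 1.34 per gene and at least 1 at 60.1% of genes. The genes with the most shared distal peaks were Tmem107 (20), Sfi1 (15), Cacna1a (13) and Fcgr3 (13), followed by Bcas3, Chd3, Lrmda, Shkbp1 and Spen with 12 each and Arhgap23, Gse1, Lrp1, Nav2, Rere and Samd4b with 11 each. Tmem107, which encodes a protein of the ciliary transition zone, lies on chromosome 11 at 69070806 to 69073293 with 14 tRNA genes within 50 kb, and Fcgr3, an Fc receptor gene, on chromosome 1 at 171051174 to 171064935 with 25. Without sites next to tRNA genes, a setting added after the values were seen, Tmem107 had 5 shared distal peaks and Fcgr3 had 1. The calcium channel gene Cacna1a (chromosome 8, 84388440 to 84640246) kept 13. Windows were taken around every annotated start, so genes with widely spaced starts covered more sequence, and the ranking was not corrected for this. Sites in sequence with further copies in the assembly were not removed.

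The X chromosome had 5.91 peaks per Mb in replicate 1 and 7.17 in replicate 2, against 15.7 and 19.4 on autosomes, and the Y chromosome had 0.170 and 0.193. These are 967 and 1173 peaks on X and 15 and 17 on Y. Among protein-coding genes, 39.6% and 40.1% of those on X had a start peak, against 59.2% and 59.9% on autosomes. The median height of start peaks on X was 0.497 times that on autosomes in replicate 1 and 0.554 times in replicate 2.

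Footprints, short protected stretches within accessible sites, numbered 140919 in replicate 1 and 167442 in replicate 2, with a median width of 9 bases in both. Peaks held 72.1% and 71.8% of them, 85.4% and 84.8% of peaks held at least 1, and the mean was 2.69 and 2.56 per peak. Of the footprints in replicate 1, 51.4% overlapped a footprint of replicate 2, and 42.9% of those in replicate 2 overlapped one of replicate 1. Starts held 54.0% and 46.5% of footprints.

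Of 36 consensus sequences, 17 were called more frequent in footprints than in their flanks, 6 less frequent and 13 neither. The largest mean log2 ratio was that of CTCF, the insulator protein, at 8.06 ± 0.05 (SD, n = 2), with 3477 footprints against 21 flank windows in replicate 1 and 3821 against 22 in replicate 2. CREB sites followed at 4.36 ± 0.19, RFX at 3.99 ± 1.77, CEBP at 3.51 ± 0.08, SP at 3.30 ± 0.03, ETS at 2.83 ± 0.24, ELF at 2.35 ± 0.01 and YY1 at 1.91 ± 0.07. The RFX value rested on 17 footprints against 4 flank windows in replicate 1 and on 24 against 1 in replicate 2. KLF sites reached 1.42 ± 0.02, NFY sites 1.04 ± 0.12 and the GRHL consensus of grainyhead-like epithelial factors 1.42 ± 0.28, a call that was lost with flanks at 50 bases and with no extension of the footprints. NRF1 sites were found in 57 footprints and 1 flank window in replicate 1 and in 55 and 0 in replicate 2, and NFI sites in 36 and 0 and in 37 and 1, so that no finite mean ratio could be given for either. AP1 sites, bound by FOS and JUN dimers, had log2 ratios of 0.81 (95% interval 0.67 to 0.96) in replicate 1 and 1.41 (1.30 to 1.52) in replicate 2, intervals that do not overlap, and were present in 0.590% and 1.07% of footprints. Weaker ratios were found for the E-boxes EBOX (0.46 ± 0.08) and TCF21_EBOX (0.38 ± 0.10) and for NFKB (0.33 ± 0.07).

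The motifs called below flanks were MEF2 at -1.65 ± 0.27 (SD, n = 2), HOXCORE at -1.57 ± 0.23, NR3C at -1.19 ± 0.06, FOX at -1.15 ± 0.26, CRX at -0.97 ± 0.49 and IRF at -0.96 ± 0.19. Footprints were richer in G and C than flanks, at 63.5% against 56.1% in replicate 1 and 61.1% against 54.3% in replicate 2. Against pooled shuffles of their own letters, a control added after the values were seen, MEF2 stood at 0.40, HOXCORE at -0.31 and FOX at -0.22, none with a call. IRF stood at 0.99 and was called above, NFKB stood at -0.48, and CRX, NR3C and NFKB were the 3 motifs called below. The 8 possible shuffles of SP differ from its consensus only in the place of the C, so they remain close to it. Pooled, they stood at 2.17 and 2.25 over flanks in replicates 1 and 2, which left SP at 1.09 over them, still called above. For SP this control therefore cannot separate base composition from SP-like sequence. On this measure GRHL (1.51), AP1 (1.37) and NFY (1.35) stood higher than SP, but for this reason SP cannot be ranked against them. When each consensus had to exceed every single shuffle, the form of this control tried first, 12 of the 17 calls above were lost, and those of CREB, CEBP, SP, ELF and AP1 remained. Of the 12, NRF1, NFI, CTCF, RFX, ETS and YY1 had a shuffle without hits in footprints or flanks, while KLF, GRHL, NFY, EBOX, TCF21_EBOX and NFKB had none. In footprints away from starts ELF stood at -0.048, and the calls of ELF, NFY, YY1 and RFX were lost. The call of NR3C was also lost there and with flanks at 200 bases, and that of TCF21_EBOX with flanks at 200 bases. The other motifs tested (P63, STAT, TEAD, RUNX, SRF, GATA, HOX13, PU1, SOX, POU, HNF4, PPAR_RXR and HNF1) were not called. In the same comparison with pooled shuffles GATA, RUNX, PU1 and POU were called above. None of them was called when every single shuffle had to be exceeded, though no shuffle of theirs lacked hits. The pooled value was subtracted as a constant, so calls against it leave out the spread among shuffles. Against flanks, calls below were made for PU1 (flanks at 50 bases, no extension, without replicate 1), SOX (flanks at 200 bases, no extension, without replicate 1), TEAD (no extension), GATA (without replicate 2) and POU (without replicate 1).

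**Figure D3:**
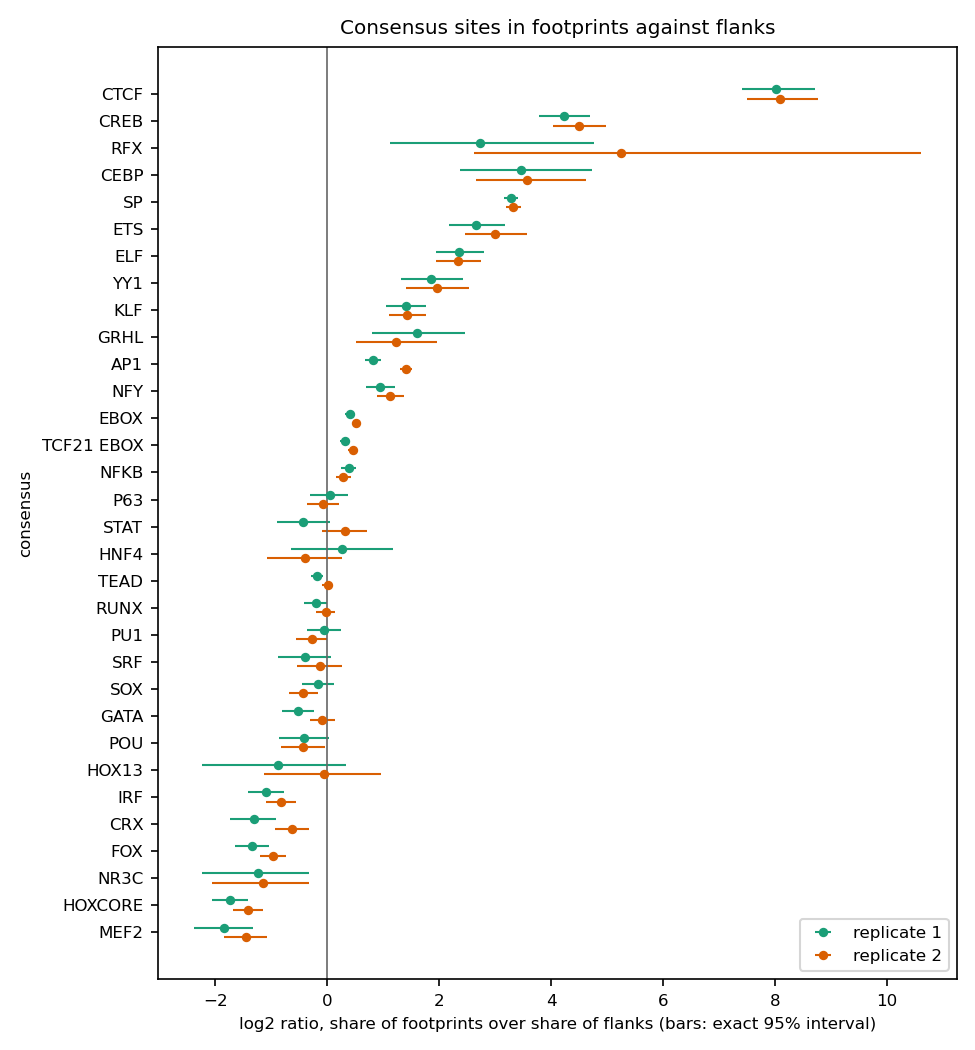
The horizontal axis is the log2 ratio of the share of footprints with a consensus over the share of flank windows, and each consensus has a point for replicate 1 (green) and replicate 2 (orange) with its exact 95% interval. CTCF lies farthest to the right at a mean of 8.06 and MEF2 farthest to the left at -1.65, while HNF1, NFI and NRF1 are not drawn because at least 1 library had 0 flank hits, and PPAR_RXR was left out for its 1 and 5 footprint hits.

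Shared distal peaks near urothelium, smooth muscle, fibroblast, endothelium and myeloid genes gave 180 pairs of list and motif. Of these, 4 passed the upper threshold and 1 the lower one. A chance number of 4.5 on each side would hold only for percentiles without ties. Many motifs were absent from the median random list, and a list without them then had a middling percentile, such as 49.65 for NRF1 near endothelium genes. Such pairs could not pass the lower threshold, so 4.5 is too high on that side. The chance number with ties was not computed for either side, so these counts cannot be set against chance. Near myeloid genes 41.7% of 24 sites held an EBOX sequence, and near fibroblast genes none of 21 held a CTCF sequence. The pairs above for CEBP and PU1 near fibroblast genes and HNF1 near urothelium genes rested on 1, 2 and 1 sites.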

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

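The tests of list length, GC content, height and width for the AP1 pattern, and those of gene density and of copy number with gene density together for the X chromosome, were chosen only after the result was seen. Footprints outside the peaks came up because they are a signal outside the main measurement: 14661 footprints of replicate 1 (10.4%) and 16532 of replicate 2 (9.87%) overlapped no peak of even the more permissive list. Of these, 98.8% and 98.8% lay within stretches with a per-site FDR of at most 0.05, and their median distance to the nearest peak was 45 and 43 bases.

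Distal sites of a single library differed in AP1 content between the animals. The AP1 consensus was present in 4.39% (exact 95% interval 3.68 to 5.19) of 2962 distal sites found in replicate 1 alone and in 12.9% (12.3 to 13.5) of 11193 found in replicate 2 alone, an odds ratio of 3.22 (2.68 to 3.87), and in 11.0% of shared distal sites. These intervals cover variation over sites only, not between animals. List length as the whole cause is argued against by lists of equal length, which gave 3.20 (2.77 to 3.70). GC content is argued against by an odds ratio of 2.93 (2.43 to 3.54) over bins of GC, and bins of height and width gave 2.77 (2.30 to 3.34). Depth itself stays open, because the equal lists were cut by peak height and reads were not equalised. A higher share of urothelial cells in replicate 2 stays open, because the height ratio of replicate 2 over replicate 1 at shared distal sites near urothelium genes stood at percentile 76.2 of random lists. A difference between the animals or in tissue handling may also contribute and was not tested, since each animal gave a single library.

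The strongest shared sites stood far above the rest, with the strongest at 36.8 times the median height of 1.60 and the fifteenth at 6.78 times. Sequence with further copies in the assembly fits most of them: 11 of the 15 consisted mostly of 32-base stretches found more than once, against 5 of 1000 other shared sites (Fisher's exact test, two-sided, p = 2.09e-19). This p-value takes sites as independent units, which they may not be, and does not cover variation between animals. Sites nearest Cox14, Ubqln1 and Hjurp held no stretch of this length found elsewhere, so exact copies within the assembly do not account for those 3. Diverged copies elsewhere in the assembly, and copies missing from the assembly, were not tested. Nuclear copies of mitochondrial DNA are argued against, as 0 sites consisted mostly of 32-base stretches of the mitochondrial genome and 1 site, nearest Gm25352, aligned to it better than all 100 of its shuffles. The design gives no group to set against these, so no biological explanation was tested; the sites were chosen for their height, after the values were seen.

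Peaks were sparser on X than on autosomes, at 0.376 times the density in replicate 1 and 0.370 times in replicate 2. Gene density as the whole cause is argued against, since X has 0.668 times as many protein-coding genes per Mb. A single X copy, modelled by keeping autosomal peaks that stay above the 5th percentile of height at 50% of their height, left a ratio of 0.612, inside the range set beforehand as undecided. Copy number and gene density together left 0.917, near 1, so a single X copy in males may account for the sparser peaks along with fewer genes. No female animals were compared, so lower accessibility of X genes cannot be told apart from copy number here.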

How the results depend on the processing

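The settings with tRNA sites left out, with distal sites counted once, with letter shuffles and with AP1 in other lists were chosen only after the result was seen. With the more permissive peak list, the mean peak number was 71696, the covered bases 15.4 Mb, the shared percent 82.2 and 65.6, Spearman's coefficient 0.928, the percent at starts 35.6, the peaks per Mb 29.1 (autosomes), 11.5 (X) and 0.477 (Y), the percent of footprints in peaks 89.9, the lists below random lists for start peaks 6, and the pairs of list and motif 2 above and 0 below. With the stronger 50% of peaks these were 21584 peaks of median width 220 bases, 5.56 Mb, 94.1% and 76.2% shared, 0.902, 61.6% at starts, and 8.89, 1.75 and 0.0113 peaks per Mb. Both follow from adding weak peaks or leaving them out. Equal lists gave 79.4% and 78.6% shared, 50% reciprocal overlap 70.3% and 57.0% with Spearman's coefficient 0.939, and start windows of 1000 bases 52.6% at starts. Per-site FDR limits of 0.01 and 0.001 gave 19.2 and 14.7 Mb. Distal windows of 100 kb gave 1 pair above and 0 below. Leaving out 1 library, the lists above random lists ranged from 2 to 4 for start peaks and from 6 to 10 for distal peaks, as a single library then decides the call. Among lists not called for start peaks, the more permissive list also moved lymphocytes from 3.36 to 12.5, endothelium from 1.19 to 8.86, adipocytes from 9.68 to 17.6 and steroid receptors from 62.3 to 93.9, and the stronger 50% moved fibroblasts from 7.72 to 19.7 and urogenital patterning from 74.2 to 43.0, with no call. Leaving out tRNA sites changed no list call. The distal calls of urothelium, immediate early and bladder function were kept under every setting run, and that of urogenital patterning was lost under 5. The AP1 odds ratio of 3.22 became 3.20 in equal lists and 3.52 (2.51 to 4.93) for sites absent from the more permissive list of the other library.

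Against pooled letter shuffles, MEF2 (0.40), IRF (0.99) and NFKB (-0.48) changed sign and 3 motifs were called below their shuffles. A first form, which asked each consensus to pass every single shuffle, gave 6 motifs above (CREB, CEBP, SP, ELF, AP1 and IRF) and 0 below and so ended 12 of the 17 calls above. In 6 of these 12 a shuffle had no hits in footprints or flanks, which left its ratio undefined or infinite. The pooled form was adopted after this was seen, and of the 17 calls above it ended that of NFKB. RFX kept its call, but its pooled shuffles gave no finite ratio in replicate 1. All 20 of its single shuffles lacked hits in footprints or flanks, so the control could not test RFX. Of the 6 calls below, the pooled form kept those of CRX and NR3C, ended those of MEF2, HOXCORE and FOX, and turned IRF into a call above. Away from starts ELF changed sign (-0.048). The cause was not tested. Apart from that first form, 10 of the 17 motifs were above under every setting. No paired analysis was possible because there is 1 group. The limits set by depth could not be given, since the absolute depth is unknown.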

Other observations

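All tests in this part were chosen only after the result was seen. Genes for transfer RNAs, which RNA polymerase III transcribes, were a class of accessible site in the bladder that the gene lists did not cover. Of 403 tRNA genes, 152 (37.7%) had a peak in replicate 1 and 175 (43.4%) in replicate 2, against 2.23% at positions 10 kb to the lower-coordinate side and 4.47% to the other side in both libraries. They made up 0.582% and 0.487% of distal peaks, and their median height stood at percentile 75.8 and 80.6 of all peaks.

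The strongest shared site lay on chromosome 17 at 39846781 to 39846920, nearest the noncoding gene Gm42418, with heights of 58.4 in replicate 1 and 59.4 in replicate 2. The next lay on chromosome 15 at 99735661 to 99736060, nearest Cox14, with 42.6 and 39.2, and on chromosome 9 at 123461901 to 123462120, nearest Lars2, with 39.1 and 34.7. At shared distal sites with the AP1 consensus, the log2 height ratio of replicate 2 over replicate 1 was 0.06 in the median, against -0.11 without it, a difference of 0.17 (95% resampling interval 0.15 to 0.19). This interval and those below cover variation over sites only, not between animals, as each animal gave 1 library. Distal sites of replicate 2 alone also held the GATA consensus more often than those of replicate 1 alone, at 2.39% against 0.979% (odds ratio 2.43, 95% interval 1.66 to 3.57), and the CTCF consensus less often, at 5.64% against 7.66% (odds ratio 0.719, 0.614 to 0.841). For sites absent from the more permissive list of the other library, which are fewer, the odds ratios were 3.16 (1.42 to 7.01) for GATA and 0.888 (0.635 to 1.24) for CTCF, and in lists of equal length 1.93 (1.44 to 2.58) and 0.641 (0.557 to 0.738). For TEAD the odds ratio was 1.31 (1.13 to 1.52), with 1.45 (1.27 to 1.66) in equal lists and 1.22 (0.937 to 1.59) for the absent sites. For SP these were 0.692 (0.496 to 0.966), 0.951 (0.690 to 1.31) and 0.738 (0.417 to 1.31). Median GC content was 55.2% in the sites of replicate 1 alone and 51.5% in those of replicate 2 alone, and these ratios were not adjusted for it. The median height ratio near the fibroblast list stood at percentile 93.7 of random lists and near the immediate early list at 81.5, both within the central 95%.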
